A study of Mus musculus with 20 samples.

How the data were processed

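The series covers 20 labelled samples of primary MEFs: 13 chromatin immunoprecipitation libraries of Pol II forms and of NELF, 4 GRO-seq libraries, and 3 polyA RNA-seq libraries of Spt5-depleted cells. Per the labels' protocols, MEFs from day 13.5 embryos were grown to passage 3, received 2 µM 4-hydroxytamoxifen for 72 h, and RNA-seq libraries were made with a TruSeq kit. The labels number the RNA-seq libraries 1 to 3 without saying that they came from separate cultures, so the spread between them may be technical. One table of RNA-seq values was analysed. The chromatin and GRO-seq samples were not analysed here.

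The table holds raw read counts per gene for the 3 Spt5-depleted libraries, per the file headers and the whole-number values as deposited. Per the submitters' processing notes, the tools used were cutadapt 1.10, TopHat, Bowtie2 2.1.0, featureCounts 1.5.0-p1 and DESeq2 1.10.1, with the mm9 genome build. The gene annotation, the strand setting and the handling of reads with several matches are not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. The table also holds a log2 fold change and an adjusted p-value per gene from the authors' own comparison, per the file headers. Its design, its direction, and any shrinkage of fold changes are not given in the sources used here. DESeq2 is named as the source of these p-values because it is the one tool of that kind in the submitters' processing notes. A further 3 columns of per-sample values carry names of no labelled sample of the series and were not used. No column could be matched to a labelled control library, so the comparison rests on the authors' fold changes and adjusted p-values as deposited.

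Of 24725 genes, 18805 had a log2 fold change and 14821 an adjusted p-value as deposited by the authors. An adjusted p-value that was NA stayed NA and out of every test. Names matched current symbols for 22417 genes and older symbols for 1007, using the NCBI RefSeq gene table of GRCm38.p6, while 1301 were unmatched. That assembly is not the one the authors used, so it served for names and for which genes neighbour each other only. A suffix such as _IMP_OVL marked 3843 loci, 2103 of them tested. Its meaning is not given in the sources used here, and it was removed to match symbols where the result was unambiguous.

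CPM were computed from the deposited counts over each library's total of 29206686, 33365515 and 17942792 reads in genes. A count of 0 allows 3 counts, or 0.103, 0.0899 and 0.167 CPM in libraries 1, 2 and 3, and such limits cover counting error only. The normalised count of a gene, used to match and bin genes by level, was the mean of size-factor-scaled counts plus 0.5, moved by minus 0.5 times the log2 fold change to the midpoint of both conditions. The deposited log2 fold changes had an SD of 0.168 over 3984 genes without an adjusted p, with none above 0.908 in size. The SD was 0.515 over tested genes at a normalised count under 100. These values go with shrinkage at weak genes, in which case their fold changes are understated and the midpoint is moved. Genes were called at an adjusted p under 0.05. The unadjusted p of each gene was bounded from above by the adjusted p times its rank over the 14821 tested genes, assuming Benjamini-Hochberg adjustment, and counts adjusted over a list alone or at an unadjusted p use that bound.

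Gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. Each of 30 lists, 8 of them markers of other cell types, was tested by two-sided Fisher exact tests of its higher and lower calls against all other tested genes, with Benjamini-Hochberg adjustment over 60 tests. Its median fold change was placed among 10000 random lists of equal size drawn within 20 bins of level, and a second set was matched on 10 bins of exonic length and 5 of level. Added after the data were seen were limma's cameraPR on signed z values from the bounded p, with a preset correlation of 0.01 or one estimated from the 3 libraries with 2 residual degrees of freedom. With an estimated correlation 7 lists passed and with the preset one 12. Negative estimates were set to 0, which treats the genes as independent. Among lists that passed, this held for the actin, NF-kappaB and unfolded protein response lists, where the estimated version was less strict than the preset one. The estimates also carry differences between the 3 libraries, such as those of library 2. They were 0.851 for oxidative phosphorylation and 0.932 for ribosomal protein genes. Symbol families were genes sharing their first 3 letters, with at least 15 tested genes. Genes of one list are not independent, so these tests describe the comparison. The named genes were Supt5, the 8 highest and 8 lowest fold changes among called genes with an official symbol and a normalised count of at least 100, up to 4 called members of each list with the smallest adjusted p, and the 2 most abundant members of each marker list. Supt4a, Hox genes, the genes of added lists and the abundant genes were named after their values were seen. One gene that the rule selects is not reported here.

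The fixed plan assumed that gene spans could be used. No annotation of the mm9 build was used here, so the deposited exonic length took their place, chosen after the file was seen. The planned GRO-seq fits, count-model fits of the RNA-seq groups and adjustment over unadjusted p-values were not run. Correlations of single Hox clusters under 10 genes used exact permutation, and larger ones 100000 permutations. Intervals used 1000 bootstrap samples of genes, apart from those named here. The interval of the Hox correlation difference used more samples, and that of the unstratified neighbour odds ratio was exact.

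The list tests were tested on simulated data over 14821 genes. Fisher tests called 1 of 200 lists without a changed gene and 99 of 100 lists of 30 with 10 changed genes, and 7 of 200 unchanged lists had a median outside the central 95% of random lists. Over 12000 simulated genes, cameraPR called 6 of 200 lists without a shift and 100 of 100 lists of 30 shifted by 1 in z. Simulated genes were independent in all of these list tests, and cameraPR was simulated with the preset correlation only. These rates therefore do not cover correlated genes or the version with an estimated correlation. A simulated library trend of 0.4 per doubling of length over 8940 genes was recovered as 0.392. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1 and edgeR 4.0.16, the last for TMM scaling and the dispersion of the counts.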

Results

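The series profiled primary mouse embryonic fibroblasts (MEFs), connective tissue cells grown from embryos, after deletion of Supt5, the gene of the transcription elongation factor Spt5. Spt5 travels with RNA polymerase II (Pol II), and the series title names Pol II processivity, the ability of the polymerase to stay on a gene, as its subject. The floxed Supt5 allele was removed by a tamoxifen-activated Cre recombinase during 72 h in 2 µM 4-hydroxytamoxifen. Control MEFs carried the recombinase without the floxed allele and received the same drug. The 20 labelled samples comprised 13 chromatin immunoprecipitation libraries, 4 libraries of nascent RNA (GRO-seq) and 3 polyA RNA-seq libraries of Spt5-depleted cells. Values of the 3 RNA-seq libraries and the authors' comparison with control cells were analysed, and the other samples were not analysed here. Library 1 held 29206686 reads counted in genes, library 2 held 33365515 and library 3 held 17942792.

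Supt5 transcripts were lower after deletion. In the authors' deposited table Supt5 fell by 2.00 on the log2 scale (DESeq2 adjusted p = 5.50e-33). Supt5 remained at 73.7 ± 6.42 CPM (SD, n = 3; CPM are read counts scaled to a common library total) in the Spt5-depleted libraries, with 74.9, 66.8 and 79.5 CPM in libraries 1, 2 and 3. Supt4a, which encodes the partner of Spt5 in the DSIF complex, had a log2 fold change of 0.47 in the authors' deposited table (adjusted p = 0.576) and did not pass the test. The header of that table gives no direction, so a negative fold change was read as lower in Spt5-depleted cells because Supt5 was negative, and Supt5 is therefore no independent check of the labels. All 3 called genes without a read in any Spt5-depleted library were negative in the authors' deposited table as well. The exons removed are not given in the sources used here, so the reads that remained do not measure the share of undeleted cells. The labels also disagree on the other Supt5 allele, null in the genotype label and wild type in the growth protocol, so whether an intact allele contributed reads is not known.

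A small part of the genes of these fibroblasts passed the test for a change in steady-state mRNA. Of 14821 genes with an adjusted p in the authors' deposited table, 680 were called at the 0.05 threshold (4.59%), 400 of them higher and 280 lower in Spt5-depleted cells. Genes without a call are not shown to be unchanged, and the smallest absolute log2 fold change called in the authors' deposited table was 0.39. The median over all tested genes was near 0 (0.01), so a shift shared by most genes would not show if scaling removed it. Among called genes with an official symbol and a normalised count of at least 100, the highest fold changes in the authors' deposited table were those of Ovgp1, an oviduct glycoprotein gene (2.14), Smpdl3b, a phosphodiesterase-like lipid enzyme gene (2.01), Col11a2, a fibrillar collagen gene (1.90), and Sfrp1, which encodes a secreted Wnt antagonist (1.84), all on the log2 scale. They were followed in the authors' deposited table by Hpx, the heme carrier hemopexin (1.83), H2-DMa of MHC class II peptide loading (1.80), the insulin-like growth factor binding protein gene Igfbp2 (1.76) and the transporter gene Slc4a11 (1.70). At the same level, the lowest values after Supt5 in the authors' deposited table were those of the limb patterning genes Hoxd13 (-1.90) and Hoxd12 (-1.70), the cGMP-dependent kinase gene Prkg2 (-1.62) and Stmn2, a microtubule regulator of neurons (-1.47). Car8 (-1.39), the interleukin 33 receptor gene Il1rl1 (-1.37) and Podnl1 (-1.35) completed that group in the authors' deposited table, and lower values at weaker genes, such as Hoxc10 (-4.63), are given with the Hox genes.

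Igfbp2 was abundant in the Spt5-depleted libraries, at 349 ± 61.6 CPM (SD, n = 3), and Sfrp1 stood at 60.8 ± 6.04 CPM (SD, n = 3). Hoxd13 stood at 11.9 ± 0.712 CPM (SD, n = 3) and Il1rl1 at 63.4 ± 20.9 CPM (SD, n = 3). The median log2 fold change in the authors' deposited table was 1.05 over genes called higher, -0.79 over genes called lower and 0.01 over all tested genes. Direction depended on the level of the gene. Of the calls in the authors' deposited table, 191 of 267 were higher at a normalised count under 100 (71.5%), 145 of 247 between 100 and 1000 (58.7%) and 64 of 166 at 1000 or more (38.6%). With an absolute log2 fold change of at least 1, 318 genes of the authors' deposited table remained, 223 higher and 95 lower. Control and Spt5-depleted cultures came from different embryos, and no batch of the control libraries is given in the sources used here.

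Genes of the integrated stress response, which act under the transcription factor ATF4, were lower as a group. In the authors' deposited table, 6 of its 30 tested members fell and 0 rose, and 8 fell when adjusted over the list alone. Chac1, a glutathione-degrading enzyme gene (-1.01), the pseudokinase gene Trib3 (-0.91), Atf4 itself (-0.59) and the alanyl-tRNA synthetase gene Aars (-0.58) had the smallest adjusted p among its members, here with their log2 fold changes in the authors' deposited table. The share of lower calls exceeded that of the other tested genes (two-sided Fisher exact test, Benjamini-Hochberg adjusted p = 0.00105 over 60 tests of 30 lists), and the list median of -0.36 lay below all 10000 random lists matched on level. Atf4 was at 219 ± 21.4 CPM (SD, n = 3) in the Spt5-depleted libraries. With genes called at an adjusted p of 0.01 in the authors' deposited table, 2 members were lower and the list no longer passed (adjusted p = 0.308). No other list passed the Fisher tests as planned, and 7 of the 30 had an unadjusted p under 0.05 in at least 1 direction.

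Interferon-stimulated genes, which act in antiviral defence, were lower as a group. In the authors' deposited table, 31 of 36 tested members were negative, with a list median of -0.49, and 4 fell while 1 rose, with the same counts when adjusted over the list alone. Cxcl10, a chemokine gene (-1.35), Ifit1, an antiviral RNA-binding protein gene (-1.13), and Parp14 (-0.87) fell in the authors' deposited table, and Tap1, a peptide transporter gene of antigen presentation, rose by 0.93 (log2). The list passed the competitive set test cameraPR with an estimated correlation (adjusted p = 0.00485) but not the Fisher test of its lower calls (adjusted p = 0.0913). Most members were weakly expressed, with a list median of 1.30 CPM, and at a normalised count of at least 100 the authors' deposited table held 0 lower calls and a list median of -0.28. Macrophage and leukocyte markers moved the same way: all 15 tested members were negative in the authors' deposited table, with a median of -0.48, and 0 were called by DESeq2, over all genes or over the list alone, with 3 lower and 0 higher at an unadjusted p under 0.05.

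NF-kappaB target and cytokine genes were also lower as a group. In the authors' deposited table, 4 of 30 tested members fell and 0 rose, or 5 lower when adjusted over the list alone. The neutrophil chemokine gene Cxcl5 (2.83-fold lower), and in log2 fold change Il1rl1 (-1.37) and the protease gene Mmp10 (-1.11) were among those 4 in the authors' deposited table. Mmp10 was at 1.06 ± 0.197 CPM (SD, n = 3) and Cxcl5 at 0.296 ± 0.152 CPM (SD, n = 3). The list passed cameraPR with a preset correlation (adjusted p = 0.0046) and with an estimated one (adjusted p = 0.00363), where a negative estimate was set to 0. The list gave an adjusted p of 0.0696 in the Fisher test of its lower calls. It passed that test at a 0.01 calling threshold (adjusted p = 0.0128), while 2 lower calls and a median of -0.10 were left in the authors' deposited table at a normalised count of at least 100. The macrophage markers named above, with their median of -0.48 in the authors' deposited table, moved with this list too.

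Actin cytoskeleton genes and targets of SRF and YAP, transcription factors that respond to actin and cell tension, were negative in 24 of 27 tested members of the authors' deposited table. Tpm4, a tropomyosin gene, fell by 0.82 and Ankrd1, a YAP target, by 0.73 (log2) in the authors' deposited table, and these 2 were also the lower calls when adjusted over the list alone. Tpm4 was at 714 ± 59.2 CPM (SD, n = 3). Cholesterol synthesis genes and SREBP targets were negative in 21 of 25 tested members of the authors' deposited table, where the sterol demethylase gene Cyp51 (-0.73) and the lanosterol synthase gene Lss (listed as Lss_IMP_OVL, -0.75) fell, or 3 members when adjusted over the list alone. Glycolysis and hypoxia genes were negative in 24 of 30 in the authors' deposited table, where the glucose transporter gene Slc2a1 (-0.74) and the hexokinase gene Hk1 (-0.60) fell, or 3 when adjusted over the list alone. The list medians were -0.33 for actin genes, -0.36 for cholesterol genes and -0.25 for glycolysis genes in the authors' deposited table, each at or below the 0.01 percentile of matched random lists. All 3 lists passed cameraPR with a preset correlation (adjusted p = 4.09e-06, 1.15e-05 and 0.0038) and with an estimated one (adjusted p = 2.94e-07, 0.0111 and 0.0111). For the actin genes a negative estimate was set to 0. None of the 3 lists passed the Fisher tests (adjusted p = 0.548, 0.535 and 0.548). Without loci that the table marks with a suffix, 1 lower call was left among the cholesterol genes in the authors' deposited table.

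Genes of endoplasmic reticulum chaperones and the unfolded protein response moved in both directions. In the authors' deposited table Xbp1, a transcription factor gene of that response (-0.68), Derl3 of protein degradation (-1.28) and the disulfide isomerase gene Pdia4 (listed as Pdia4_IMP_OVL, -0.53) fell, while the co-chaperone gene Dnajb9 rose by 0.92 (log2). These were 3 lower and 1 higher of 21 tested members, with the same counts adjusted over the list alone. The list passed cameraPR on the lower side (adjusted p = 0.0448 preset, adjusted p = 0.0408 with an estimated correlation, where a negative estimate was set to 0). The share of lower calls did not pass its Fisher test (adjusted p = 0.103). Derl3 was near the floor, at 0.213 ± 0.00911 CPM (SD, n = 3), while Xbp1 was at 72.2 ± 2.72 CPM (SD, n = 3). Heat shock genes had 1 call each way among 20 tested members in the authors' deposited table, likewise when adjusted over the list alone: the inducible Hspa1a rose by 1.15 and the constitutive Hspa8 fell by 0.53 (log2).

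Within the transcription machinery few genes other than Supt5 were called. Of 39 tested Pol II pausing and elongation factor genes in the authors' deposited table, Supt5 fell and Eaf2, a partner of ELL elongation factors, rose by 0.99 (log2), the same pair as when adjusted over the list alone. All 12 tested Pol II subunit genes were positive in the authors' deposited table, with a median of 0.26, and 1, Polr2l, rose by 1.06 (log2), also when adjusted over the list alone. Polr2l was uneven between libraries, at 194 ± 124 CPM (SD, n = 3). The Pol II subunit list passed cameraPR with a preset correlation (adjusted p = 0.0315) and not otherwise (adjusted p = 0.582 with an estimated correlation). Splicing genes had 1 lower call among 36 tested, Sf3b3 (-0.46), in the authors' deposited table, over all genes and adjusted over the list alone. Genes of 3′ end processing and termination had 0 calls among 22 tested in the authors' deposited table by DESeq2, and 0 at an unadjusted p under 0.05.

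Replication-dependent histone genes, whose transcripts normally lack a polyA tail, had 3 higher and 0 lower calls among 29 tested in the authors' deposited table, also when adjusted over the list alone. Hist1h4a rose by 1.45, Hist1h2be (listed as Hist1h2be_IMP_OVL) by 1.35 and Hist2h2be by 1.02 (log2) in the authors' deposited table. Hist2h2be was at 4.91 ± 0.352 CPM (SD, n = 3), and near-identical histone genes can share reads. Deposited exonic lengths were 2510 bases for Hist1h2be and 2618 for Hist2h2be, against 312 for Hist1h4a and a list median of 537. Where in these genes the reads lay was not tested, so the calls do not show a change in polyA tailing. The median log2 fold change of 0.24 lay at the 99.1 percentile of random lists matched on level. Matched on exonic length and level, that median lay at the 96.08 percentile, inside the central range of those lists (-0.06 to 0.25). The list passed cameraPR with a preset correlation (adjusted p = 0.00217) but lost its call otherwise (adjusted p = 0.207 with an estimated correlation), and its Fisher test gave an adjusted p of 0.364. At a normalised count of at least 100, 1 higher call was left in the authors' deposited table.

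Growth and damage genes showed single changes. Among 35 tested p53 targets in the authors' deposited table, the death receptor gene Fas rose by 0.97 and the apoptosis effector gene Perp by 0.87 (log2), the same 2 when adjusted over the list alone. The p53 list had a median of -0.05 and a mean of 0.04, of opposite sign, in the authors' deposited table. Of 15 tested senescence genes in the authors' deposited table, 2 rose and 2 fell, with 2 higher and 3 lower when adjusted over the list alone. Among them the protease inhibitor gene Serpine2 (1.04) and Igfbp3 (0.90) rose and the chromatin protein gene Hmga2 (-1.18) fell in the authors' deposited table. Of 31 tested immediate early genes, the authors' deposited table had Junb higher (0.54) and Klf2 lower (-0.77), likewise adjusted over the list alone. None of these lists passed its Fisher tests (smallest adjusted p = 1, 0.318 and 1) or cameraPR.

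Several lists had 0 calls by DESeq2 in the authors' deposited table, over all genes and adjusted over the list alone. Of 56 tested nuclear-encoded oxidative phosphorylation genes, 53 were positive in the authors' deposited table, with a median of 0.25 above all random lists, and 1 had an unadjusted p under 0.05. That list passed cameraPR with a preset correlation (adjusted p = 0.0117) and lost its call otherwise (adjusted p = 0.931 with an estimated correlation). Fibroblast extracellular matrix genes had a median of 0.13 over 40 tested in the authors' deposited table, with 5 higher and 1 lower at an unadjusted p under 0.05, and that median also lay above all random lists, while cameraPR did not pass (adjusted p = 0.260 preset, adjusted p = 0.931 with an estimated correlation). Mitotic and G2/M genes had a median of -0.10 over 35 tested, and DNA replication and G1/S genes one of -0.06 over 42 tested, in the authors' deposited table, each with 1 lower at an unadjusted p under 0.05. Their medians lay at the 1.33 and 6.01 percentiles of random lists matched on level, and neither list passed cameraPR (smallest adjusted p = 0.153 and 0.342). Cytosolic ribosomal protein genes had a median of 0.01 over 78 tested in the authors' deposited table, with 39 positive, 39 negative and 1 lower at an unadjusted p under 0.05. Among random lists that median lay at the 85.8 percentile when matched on level and at the 0.05 percentile when matched on exonic length and level, where the central 95% of random lists ran from 0.06 to 0.18. Imprinted growth genes had a median of -0.04 and a mean of 0.003 over 14 tested in the authors' deposited table, with 1 higher at an unadjusted p under 0.05.

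**Figure D1:**
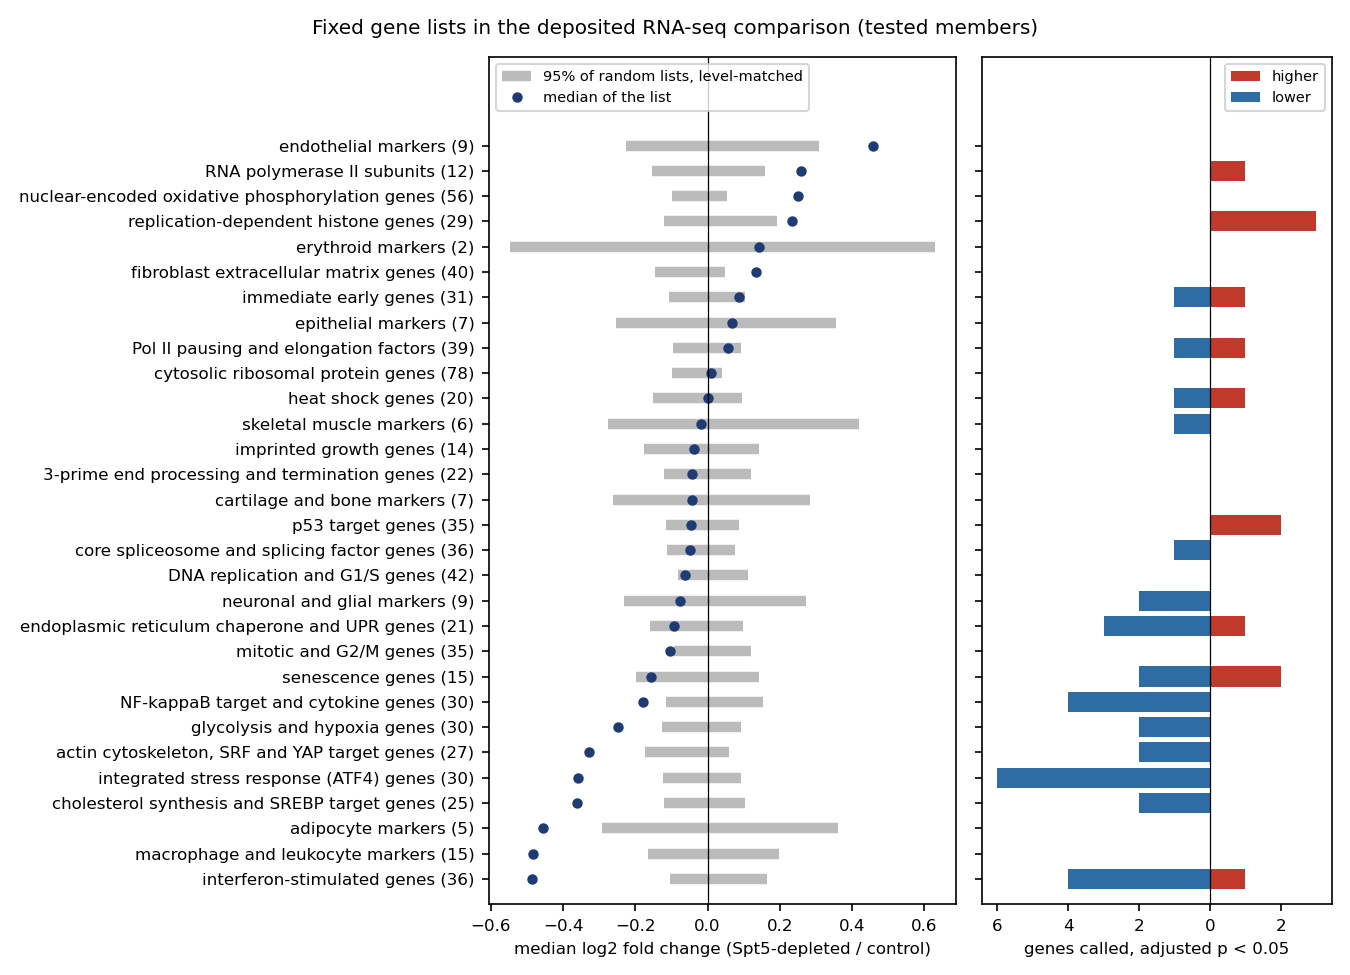
Median log2 fold change (left, points) of the 30 fixed gene lists in the authors' deposited table, with the central 95% of 10000 level-matched random lists as grey bars, and the number of members called higher or lower (right). The integrated stress response list has 6 lower calls, and the median of interferon-stimulated genes is -0.49.

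Markers of other cell types were measured to describe the makeup of the cultures. In the authors' deposited table the macrophage list lost its cameraPR call when its correlation was estimated (adjusted p = 0.00294 preset, adjusted p = 0.597 with an estimated correlation), as did adipocyte markers, negative in 5 of 5 tested (adjusted p = 0.0418 preset, adjusted p = 0.582 with an estimated correlation). Of the adipocyte markers, 0 were called by DESeq2 in the authors' deposited table, 1 was lower when adjusted over the list alone, and 2 were lower and 0 higher at an unadjusted p under 0.05. Lyz2, the macrophage lysozyme gene, was at 111 ± 96.6 CPM (SD, n = 3), so libraries of the same genotype differed widely. Among 9 tested neuronal and glial markers, Stmn2 (-1.47) and the tubulin gene Tubb3 (-0.61) fell in the authors' deposited table, with 1 higher and 2 lower adjusted over the list alone. Among 6 skeletal muscle markers the actin gene Acta1 (-1.08) fell in the authors' deposited table, also adjusted over the list alone. Endothelial, epithelial, erythroid, and cartilage and bone markers had 0 calls by DESeq2 in the authors' deposited table over 9, 7, 2 and 7 tested genes, with medians of 0.46, 0.07, 0.14 and -0.04. At an unadjusted p under 0.05 these 4 lists had 1, 1, 0 and 2 higher and 0, 0, 0 and 1 lower in the authors' deposited table, and 1 cartilage and bone marker was higher when adjusted over the list alone. The endothelial median lay at the 99.8 percentile of random lists, without passing cameraPR (adjusted p = 0.412 preset, adjusted p = 0.582 with an estimated correlation). Kdr, an endothelial receptor gene, was at 19.2 ± 10.4 CPM (SD, n = 3), and Krt18, an epithelial keratin gene, was at 14.7 ± 8.82 CPM (SD, n = 3).

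Hox genes, which set position along the body axis and the limb, changed in a direction that followed their place in the clusters. Of 12 tested genes of paralog groups 10 to 13, 11 fell in the authors' deposited table, with a median of -1.19, and Hoxc13 (0.00, adjusted p = 0.999) did not pass. Of 18 tested genes of groups 1 to 7, 9 rose and 0 fell in the authors' deposited table, with a median of 0.68, led by Hoxb6 (1.11), Hoxa2 (1.09), Hoxb5 (0.96) and Hoxa5 (0.96). The 7 tested genes of groups 8 and 9 had 0 calls by DESeq2 and a median of 0.02 in the authors' deposited table. Adjusted over each group list alone, 1 gene of groups 8 and 9 was lower in the authors' deposited table. In the same way 14 genes of groups 1 to 7 were higher and 11 of groups 10 to 13 lower. These groups were formed after the values were seen, so the counts adjusted over a group alone are descriptive and add no calls. Hoxc10 had the lowest log2 fold change of the family in the authors' deposited table (-4.63, adjusted p = 4.63e-56). Hoxc10 was at 0.167 ± 0.0658 CPM (SD, n = 3) in the Spt5-depleted libraries, and Hoxb13, Hoxc11 and Hoxc12 had 0 reads in all 3, which allows up to 0.103, 0.0899 and 0.167 CPM in libraries 1, 2 and 3 by counting error. Fitted folds of those 3 genes depend on the model, and without them 8 of 9 genes of groups 10 to 13 were lower with a median of -1.10 in the authors' deposited table.

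The Hox family was singled out after its values were seen, through a test of 151 symbol families of at least 15 tested genes. It passed in both directions among 39 tested symbols (9 higher, adjusted p = 0.000108; 12 lower, adjusted p = 1.23e-09, Fisher exact tests). Across 37 Hox genes, which are not independent replicates, the Spearman correlation of paralog number with the fold change of the authors' deposited table was -0.83 and the Pearson correlation was -0.72. The permutation p of the Spearman correlation was 1e-05, the smallest that 100000 permutations can give. Within clusters the correlation was -0.88 in HoxA (permutation p = 0.00087), -0.77 in HoxC (exact permutation p = 0.0214) and -1 in HoxD (exact permutation p = 4.96e-05). It was -0.30 in HoxB (exact permutation p = 0.437), which did not pass. Hoxb13, without a read, was the only negative tested HoxB gene in the authors' deposited table. The HoxC value likewise includes Hoxc11 and Hoxc12, which had no read. Over the 34 tested Hox genes with a read, all clusters together, the Spearman correlation was -0.81. The body region of the embryo tissue behind each culture is not given in the sources used here, and the 2 genotypes came from separate embryos.

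**Figure D2:**
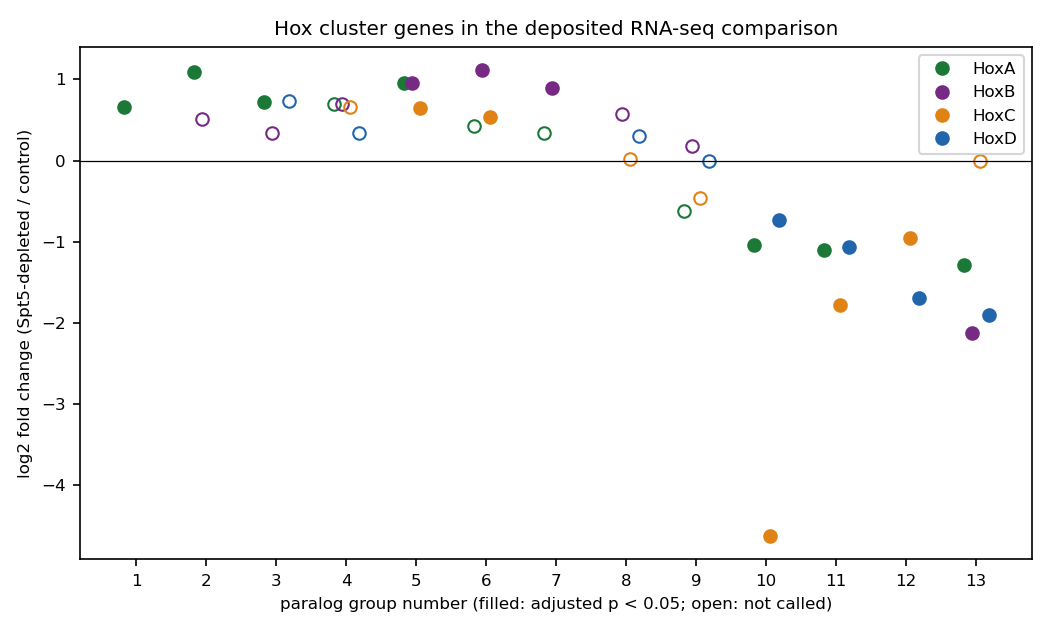
Log2 fold change of 37 Hox genes in the authors' deposited table against paralog group number, coloured by cluster, with filled points for genes called at the 0.05 threshold and open points for the rest. Groups 1 to 7 have 9 higher and 0 lower calls, and groups 10 to 13 have 11 lower calls.

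Long and short transcripts were compared because the series title concerns processivity. Shorter transcripts had slightly higher fold changes: the median log2 fold change in the authors' deposited table was 0.14 over 1186 genes with under 1 kb of counted exon, 0.08 over 3378 genes of 1 to 2 kb and -0.04 over 3672 genes of 4 to 8 kb. It was -0.01 over 5934 genes of 2 to 4 kb and 0.01 over 651 genes of 8 kb or more in the authors' deposited table. From the shortest bin to the longest, 22, 116, 175, 80 and 7 genes were called higher in the authors' deposited table. In the same order 7, 52, 146, 71 and 4 were called lower. Across 14821 genes, which are not independent replicates, the Spearman correlation of exonic length with the fold change of the authors' deposited table was -0.16 (95% bootstrap interval -0.17 to -0.15). Exonic length is not the distance that the polymerase travels, and genomic spans were not used here. Libraries of the same genotype differed with exonic length more strongly than the comparison did.

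The Spt5-depleted libraries expressed a fibroblast profile, led by the matrix genes Fn1 and Col1a1, which encode fibronectin and a collagen I chain. Col1a1 was at 11300 ± 2829 CPM (SD, n = 3) and Sparc, a matrix-binding glycoprotein gene, at 7844 ± 104 CPM (SD, n = 3). Fn1 was at 11590, 38549 and 9730 CPM in libraries 1, 2 and 3. A mean of at least 1 CPM was reached by 12401 genes and of at least 10 CPM by 8940. Library 2 stood apart from the others: the Pearson correlation of log2(CPM + 1) across genes was 0.995 between libraries 1 and 3, 0.985 between 1 and 2, and 0.971 between 2 and 3. Spearman correlations of those pairs were 0.981, 0.976 and 0.966. Of genes at 10 CPM or more, 27.8% differed more than 2-fold between libraries 2 and 3, against 1.51% between libraries 1 and 3. The log2 ratio of library 2 to library 1 rose with exonic length (Spearman 0.74 across genes), and that of library 3 to library 1 fell (-0.60). The common biological coefficient of variation was 0.364 (edgeR), and the authors' comparison could not be refitted without library 2.

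**Figure D3:**
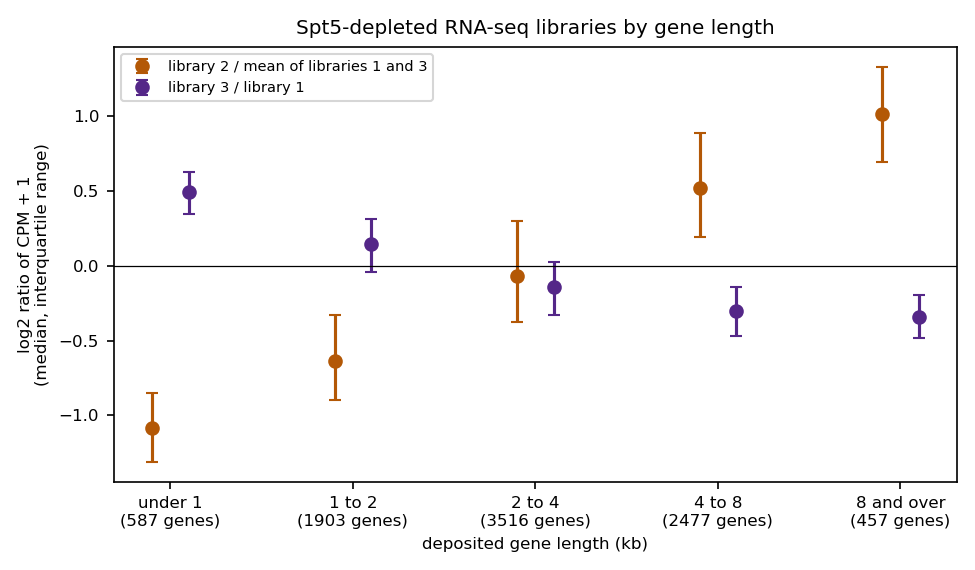
Log2 ratio of CPM + 1 (median as points, interquartile range as bars) of Spt5-depleted library 2 to the mean of libraries 1 and 3, and of library 3 to library 1, in 5 bins of deposited gene length in kb, over 8940 genes at 10 CPM or more. The median for library 2 goes from -1.09 under 1 kb to 1.01 at 8 kb and over.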

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

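The number of called genes followed the calling rule. Against 680 calls (400 higher, 280 lower, 58.8% higher), an adjusted p of 0.01 left 374 (226 and 148) and an absolute log2 fold change of at least 1 left 318 (223 and 95, 70.1% higher). A normalised count of at least 100 left 413 (209 and 204, 50.6% higher), from fewer genes of low level. A threshold of 0.1, a normalised count of at least 10, and leaving out marked loci gave 955, 658 and 600. The count of 1 list past the Fisher tests did not move under the alternatives fixed before the data were examined, but at a 0.01 threshold that list was the NF-kappaB list (adjusted p = 0.0128) and the integrated stress response list was past it no longer (adjusted p = 0.308, on 2 calls). With cameraPR, chosen after seeing the data, 12 lists passed with a preset and 7 with an estimated correlation; it tests all members, not only calls, and the cause was not otherwise tested. Symbol families past the threshold numbered 2 in both settings, Hox and Zfp over all genes and Hox and Pig at a normalised count of at least 100. The correlation of fold change with exonic length (-0.16) and that of Hox fold change with paralog number (-0.83) kept direction under every alternative run. Among single lists and genes, 462 values stayed within their spread or side of the threshold, 20 moved, 1 gained and 1 lost its call, and 0 reversed. That tally includes values that could hardly move. Counts of 0 that stayed 0 entered as unchanged, and centring shifted each list median by only 0.01, the median of all tested genes. A list median could enter as reversed only if its list had passed a test.

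The mean pairwise Pearson correlation of 0.983 between libraries was 0.900 over genes at 10 CPM or more, which leaves out genes near 0, and ranged from 0.971 to 0.995 when each replicate was left out. Genes at 1 CPM or more ranged from 12328 to 12417 in the same way. No paired analysis was possible because no column could be matched to a labelled control RNA-seq library, so fits with DESeq2 or edgeR, their filters, leaving out a replicate, and adjustment over unadjusted p-values were not run for the comparison. GRO-seq alternatives and those on gene span were not run either. Library 3, with 17942792 reads, sets the lowest level seen, and genes with few reads rest on the authors' model.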

Other observations

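The NRF2, glycosylphosphatidylinositol (GPI), tRNA synthetase, limb and craniofacial gene lists were chosen only after the results were seen. So were the symbol families, the cameraPR tests, the test of the most abundant genes and the tests on genes called lower and within strata of level. Targets of NRF2, the transcription factor of the oxidative stress response, had 6 lower and 0 higher calls among 22 tested in the authors' deposited table, on a list drawn up after some of its calls were seen. Heme oxygenase gene Hmox1 (-0.77), Mgst1 (-0.72), Gclm of glutathione synthesis (-0.72), Sqstm1 (-0.68), Nqo1 (-0.66) and Srxn1 (-0.64) were those 6 in the authors' deposited table. Hmox1 stood at 239 ± 29.9 CPM (SD, n = 3). Genes of GPI anchor synthesis, which attach proteins to the membrane, had 4 higher and 0 lower calls among 26 tested in the authors' deposited table, on a list drawn up after these calls were seen. Over all genes the family of Pig symbols did not pass (4 higher of 20 tested in the authors' deposited table, Fisher exact test, adjusted p = 0.136 over 151 families). Pigt (0.81), Pigf (listed as Pigf_IMP_OVL, 0.65), Pigm (0.56) and Pigk (0.53) were those 4 in the authors' deposited table. Of 20 cytosolic tRNA synthetase genes, 1, Aars (-0.58), was lower in the authors' deposited table.

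Zinc finger genes with a Zfp symbol were called rarely: 0 of 340 tested were higher and 2 lower in the authors' deposited table, fewer higher calls than among other genes (Fisher exact test, adjusted p = 0.0135 over 151 families). At a normalised count of at least 100 the Zfp family did not pass. Among limb regulators outside the Hox clusters, the hindlimb genes Tbx4 (-2.86) and Pitx1 (-2.19) fell in the authors' deposited table. The forelimb gene Tbx5 had a log2 fold change of -0.12 (adjusted p = 0.942) and Isl1 one of -0.12 (adjusted p = 0.979) in the authors' deposited table. Tbx4 was at 0.854 ± 0.371 CPM (SD, n = 3), Pitx1 at 1.53 ± 0.492 CPM (SD, n = 3) and Tbx5 at 7.24 ± 1.14 CPM (SD, n = 3). Isl1 was at only 0.197 ± 0.0887 CPM (SD, n = 3), so its lack of a call says little.

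Hox genes of high paralog number were lower and those of low number higher in the Spt5-depleted cultures. Their exonic length argues against a length effect: its rank correlation with the fold change of the authors' deposited table was -0.013, against -0.83 for paralog number (bootstrap 95% interval of the difference in size 0.394 to 0.869). A candidate explanation is a more anterior or less distal body-region makeup of the embryo tissue behind these cultures. It was tested with 22 craniofacial mesenchyme genes, a list added to the fixed ones after results were seen. Of these genes 14 were at 1 CPM or more, with Six2 the most abundant at 7.64 CPM. Their median lay at the 69.2 percentile of matched random lists, with Pax3 (1.63) and Alx1 (1.04) higher among 17 tested in the authors' deposited table. That percentile lies between the bounds set for and against a makeup difference. Another value goes with such a difference: cameraPR, which weighs all members, placed the list on the higher side (unadjusted p = 0.0120 preset, unadjusted p = 0.0104 with an estimated correlation). The falls of Tbx4 and Pitx1 have the same direction, but these genes were listed after the results were seen and are no independent support. Alx1 was put on the list after its value was seen, and without it cameraPR gave an unadjusted p of 0.0528 and 0.0740. The evidence is mixed, so a makeup difference and an effect of Spt5 loss on Hox genes cannot be told apart, since genotype and embryo go together.

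Library 2 differed from the other Spt5-depleted libraries, with an SD of 0.775 of the log2 ratio to them. The 10 most abundant genes took 10.8% of the counts of library 2, against 6.89% in library 1 and 6.23% in library 3. A few genes taking most of the counts would shift all other genes by one offset, but over genes other than the 10 most abundant the median log2 ratio was higher by 2.097 at 8 kb or more than under 1 kb (95% interval 2.04 to 2.16), against an SD of 0.373 between libraries 1 and 3. That gap restates the length trend, which was known when this test was chosen. Exonic length explained 0.507 of the variance, which is consistent with a difference in library preparation or RNA integrity. Extracellular matrix genes had a median log2 ratio of 0.27 after the length trend was removed, at the 100 percentile of random lists of 39 genes matched on level. Those random lists were not matched on length, and the matrix genes were long (median 5022 bases over 40 tested). A culture difference may contribute, but a remaining length or preparation effect is not excluded, and the labels do not show separate cultures. Fn1 (0.94) and Thbs1 (1.21) were higher and Vim (-0.47) and Actb (-0.64) lower on that corrected log2 scale in library 2.

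Among genes of the authors' deposited table at a normalised count under 100, 71.5% of calls were higher. Loci marked with a suffix do not account for it, since 68.6% of calls were higher without them. Reads running on from an expressed neighbouring gene may contribute: 137 of 188 genes called higher had a neighbour at 10 CPM or more (72.9%), against 2530 of 3954 not called (64.0%; odds ratio 1.51, 95% interval 1.08 to 2.14, Fisher exact p = 0.0126). The share among genes called lower was 38 of 76 (Fisher exact p = 0.000531 against those called higher), and within strata of level the odds ratio was 1.45 (95% interval 1.03 to 2.1). Most genes called higher at this level share that neighbourhood with genes not called, strand and genomic distance were not used here, and activation of weak genes after Spt5 loss stays open.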
